A study of Mus musculus with 12 samples.

How the data were processed

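RNA was measured in 12 libraries from articular cartilage and growth plate of mouse knees, 6 per tissue. Per the labels' protocols, knees were frozen, sectioned and captured by laser, RNA was isolated with a column kit, and stranded total RNA libraries were made with a low-input kit. The deposited table holds 1 column per library in RPKM (reads per kilobase of transcript, scaled to library size), which the authors normalised further and named NRPKM per the file headers; how this was done is not given in the sources used here. The genome build was mm10 per the submitters' processing notes. The aligner, the counting tool, the annotation and the rule by which genes were listed are not given in the sources used here. Values under 1 appear to have been set to 1, since 1299 to 2823 genes per library equal 1 and none lies below. Whole reads could not be recovered from the values, so depth is unknown, and no interval or detection limit from counting is given. The most abundant listed gene held 24.0 to 45.1 percent of the summed values of a library. Of 14712 listed genes, 14293 matched GENCODE M21 by identifier, which gave coordinates and biotypes on mm10; symbols are those of the file. Strand use in counting is not given in the sources used here, so overlapping, antisense and near-identical genes, such as the globin and small nuclear RNA copies, are uncertain.

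Groups came from the genotype and tissue labels: control or mutant, in articular cartilage or growth plate. The header of the file names a reporter allele for the Sox9 columns that the labels do not. Each mutant was matched to the control of the same floxed alleles, day and tissue, which gave 3 pairs per tissue. Labels number no replicates, so only this matching was used. The fits, comparisons, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined.

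Values were taken as log2(value + 1) and fitted with limma 3.58.1 (robust empirical Bayes with a mean trend, statmod 1.5.0) in R 4.3.3 over all 12 libraries. The mutant effects were fitted with the set as a block and 4 cells of tissue by Cre. The control tissues and the tissue difference of the mutant effect were fitted with a block for each genotype and day. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The planned filter, a mean value of at least 1, removed 0 genes and so tested nothing. The design had planned a count test for counts and this limma test for normalised values, and the latter applied; the alternatives written for a count tool or count scaling did not apply. The comparison of days and that of genotypes at day 14 have 1 library per cell and were described without a test. The description used differences of log2 ratios and the percentile of a list's median among 10000 random lists matched on mean expression. Random lists pick genes one by one, while genes of a list vary together. A shift in 1 library can therefore give an extreme percentile, and the percentiles do not measure certainty.

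Gene lists were tested with camera at a preset correlation of 0.01, with a Benjamini-Hochberg adjustment over the 20 lists with measured members, and again with an estimated correlation and with fry. The lists covered cartilage matrix, chondrocyte transcription factors, articular and superficial zone, prehypertrophic and hypertrophic genes, growth plate signalling, osteoblasts and osteocytes, matrix degrading enzymes, fibroblasts and tendon, Wnt and BMP signalling, cell cycle, immediate early and stress genes, hypoxia and glycolysis, erythroid cells, neutrophils, macrophages, osteoclasts, B cells, endothelial cells, adipocytes and skeletal muscle. A list of mitochondrially encoded genes had 0 of 13 members in the table and was not tested. The named genes were Sox9 and Sox8; the 6 genes with the largest rise and the 6 with the largest fall among called genes of the same direction in all 3 pairs with a mean value of at least 10 and no predicted-gene symbol (4 each for the tissue difference); and up to 2 called members of each list with the largest change. For the described comparisons they were the 4 genes per tissue and direction with the largest difference and a mean of at least 50, whatever their symbol. Other members named where their list is described, such as Col2a1, Ihh, Col1a1, Alpl and Runx1, Acan levels per library, Xist, the Y-linked genes and the shared articular and growth plate genes were chosen after their values were seen. Of the described genes, small nuclear and predicted RNAs are named in the closing section only.

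Alternatives were another added value, quantile normalisation, no set block, a block for each matched pair (or the set with 4 cells), the Sox9 sets alone, the 6 compared libraries alone, and leaving out each library in turn. A mean value of at least 5, scaling to the median ratio over genes above 1 in every library, and protein-coding genes alone were chosen after seeing the data. The fit was tested on simulated data with the fitted values and residual spread of the real genes, normal errors and 200 changed genes per run in 5 runs over 14712 genes. At a log2 change of 2 it recovered 85.6 percent of changed genes for the articular mutant effect, 88.8 percent for the growth plate effect, 79.6 percent for the control tissues and 48.4 percent for the tissue difference. At a log2 change of 1 these shares were 40.4, 34.0, 33.6 and 5.20 percent. False calls were 4.19, 4.72, 3.67 and 3.39 percent of calls, in the same order. The simulated data follow the fitted model, without correlation between genes, shared animals or a floor at 1. These shares therefore do not test how the fit behaves under those conditions. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.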

Results

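Bulk RNA sequencing was carried out on articular cartilage and growth plate cartilage captured by laser from knees of mice aged 3 months. The series addresses how loss of the chondrocyte transcription factor Sox9, alone or with its relative Sox8, changes gene expression in these adult cartilages. Each tissue had 3 control libraries with floxed alleles and no Cre, and 3 mutant libraries that also carried AcanCreERT2, an inducible Cre placed at the aggrecan gene Acan. The 12 libraries formed 3 sets of 4: Sox9 alleles at day 7, Sox9 alleles at day 14, and Sox8 with Sox9 alleles at day 14. A reporter allele is named in the column headers for the Sox9 sets only. The event from which days were counted is not given in the sources used here. Each genotype, day and tissue had 1 library, so the 3 mutants of a tissue were not repeats of 1 condition, and the spread between sets was part of the error. The labels do not tie regions to animals, so the p-values measure only the spread between these libraries. Regions that share an animal would make the p-values of the mutant effects within a tissue too small. The control tissues and the tissue difference of the mutant effect were compared within genotype and day. That block takes up a level shared by both regions. Values were the authors' normalised RPKM for 14712 genes, with 1299 to 2823 genes per library listed at the lowest value, 1. Read depth is unknown. Log2 fold changes are on the log2(value + 1) scale, which understates the change of low genes.

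Sox9 (chromosome 11, 112782224 to 112787760, mm10) was lower in the mutant than in the matched control in 5 of the 6 pairs. In articular cartilage it went from 408 to 304 in the Sox9 day 7 pair and from 349 to 309 in the Sox9 day 14 pair. In the Sox8 Sox9 pair it was 213 in the articular control and 282 in the articular library labelled Sox8 Sox9 mutant, against that label. In growth plate it went from 314 to 236 at day 7, from 335 to 148 at day 14, and from 308 to 36.0 in the Sox8 Sox9 pair. Sox8 (chromosome 17, 25565892 to 25570686) was lower in the mutant in all 6 pairs. Its articular values went from 23.2 to 5.16, from 17.8 to 1.63, and from 15.3 to 8.66 in the library labelled Sox8 Sox9 mutant. Its growth plate values went from 29.0 to 6.71, from 21.7 to 4.93 and from 28.8 to 1.89, in the same order. Which exons are floxed is not given in the sources used here, and a value covers the whole gene, so transcripts left after recombination also count. Acan, which carries the Cre and so is not an independent readout, lay between 1038 and 2599 in articular controls and between 316 and 430.0 in articular mutants. In growth plate it lay between 1694 and 2887 in controls and between 27.8 and 288.5 in mutants.

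**Figure D1:**
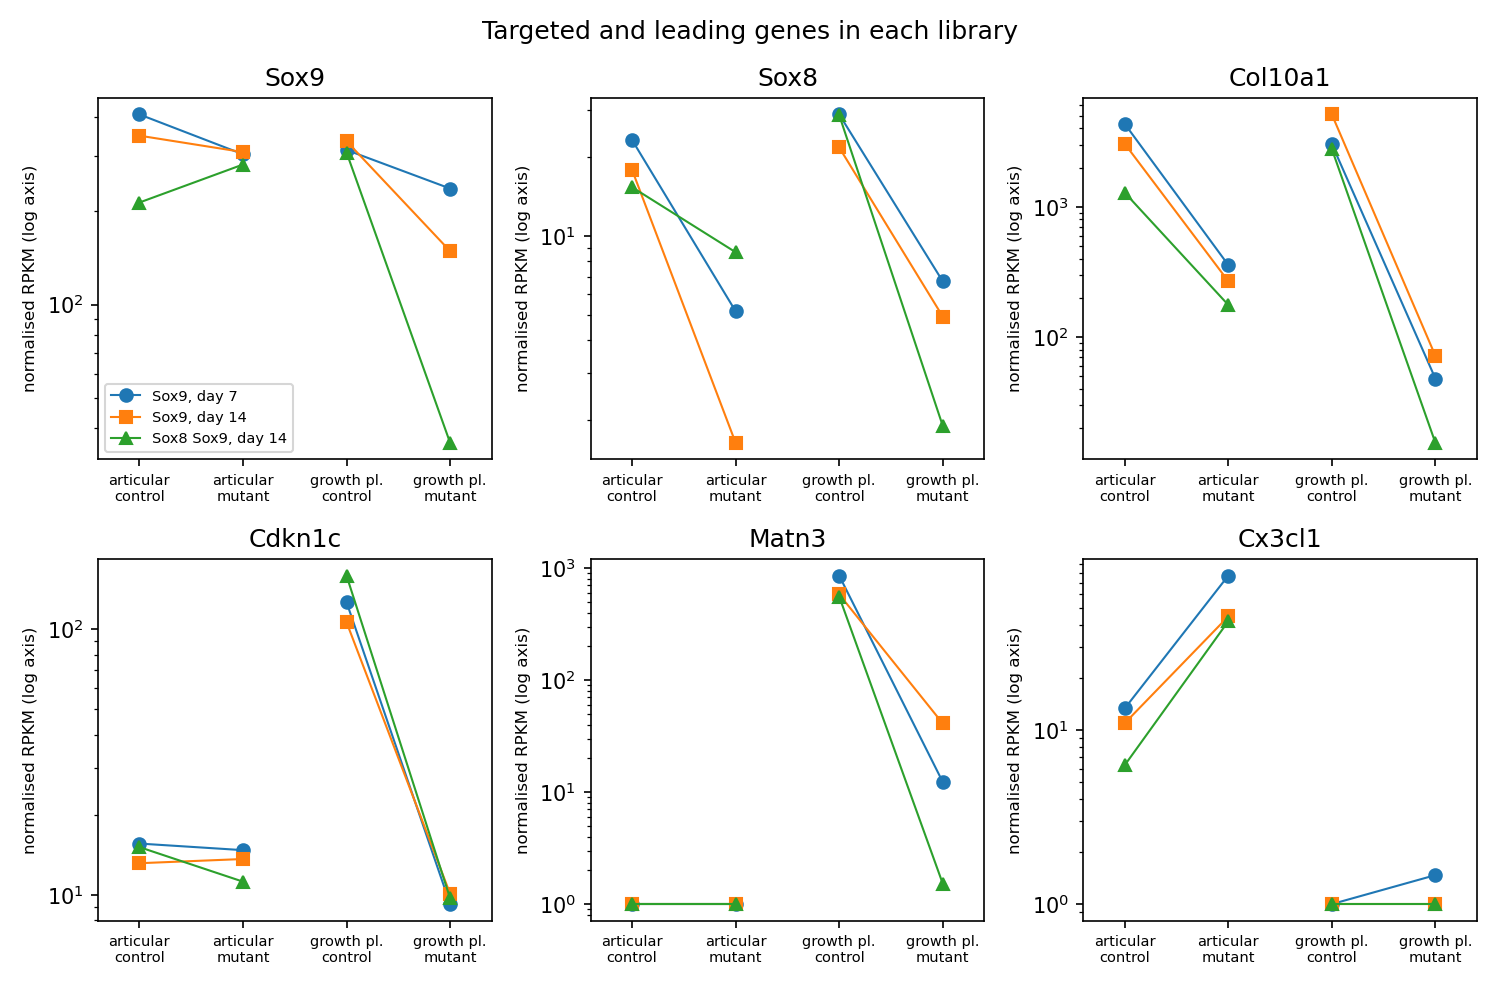
Normalised RPKM (log axis) of Sox9, Sox8, Col10a1, Cdkn1c, Matn3 and Cx3cl1 in each of the 12 libraries; each line joins a control to the mutant library of the same genotype set, day and tissue. Sox9 goes from 308 to 36.0 in the Sox8 Sox9 growth plate pair and from 213 to 282 in the articular pair labelled Sox8 Sox9.

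Mutant and control articular cartilage differed in a small group of genes, among them Col10a1 and the Wnt antagonist genes Sfrp5 and Frzb on the lower side. Col10a1, the collagen X gene of hypertrophic chondrocytes (chromosome 10, 34389981 to 34397085), fell from 2886 ± 1529 to 268 ± 90.5 (mean ± SD, n = 3 libraries each), a log2 fold change of −3.32 ± 0.35 SE (limma, Benjamini-Hochberg adjusted p = 0.00523). Sfrp5, a secreted Wnt antagonist (chromosome 19, 42197971 to 42202252), fell from 111 ± 27.0 to 9.76 ± 2.78, a log2 fold change of −3.38 ± 0.40 (limma, Benjamini-Hochberg adjusted p = 0.0149). Cx3cl1, the chemokine fractalkine (chromosome 8, 94772009 to 94782427), rose from 10.2 ± 3.57 to 54.6 ± 19.4, a log2 fold change of 2.32 ± 0.22 (limma, Benjamini-Hochberg adjusted p = 0.00259). Vcan, which encodes the large proteoglycan versican, rose from 16.1 ± 6.41 to 44.7 ± 10.6, and Lpl, which encodes lipoprotein lipase, rose from 12.6 ± 3.09 to 30.2 ± 7.10.

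With limma and Benjamini-Hochberg adjustment over 14712 genes, 52 genes passed an adjusted p of 0.05 in articular cartilage, 23 higher and 29 lower in mutants, and all 52 had the same direction in the 3 pairs. Calls were made from these same pairs, so a shared direction, here and in the other comparisons, gives no separate support. The median log2 fold change of all genes was 0.13. Scaling to the median ratio called 46 genes, 12 higher and 34 lower, and quantile normalisation called 47, 11 higher and 36 lower. The other named falls were Cpm, which encodes carboxypeptidase M (−2.43 ± 0.23), Stc2, which encodes stanniocalcin 2 (−2.97 ± 0.44), the pseudogene Itih5l-ps (−3.24 ± 0.41) and Omd, which encodes osteomodulin (−2.05 ± 0.34). Tnfaip2 rose by 1.25 ± 0.21 and Sbno2 by 1.15 ± 0.20. Sox9 had a log2 fold change of −0.06 ± 0.43 (limma, Benjamini-Hochberg adjusted p = 0.993) and Sox8 one of −1.86 ± 0.43 (adjusted p = 0.133), and neither passed.

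No member of the 24 cartilage matrix genes passed over all genes in articular cartilage, and 9 were lower when adjusted over the list alone. These included Ucma (−3.18), Col9a2 (−2.33), Col11a2 (−1.39) and Acan (−2.33), which carries the Cre and is not an independent readout. The list had a median of −1.06 (camera, Benjamini-Hochberg adjusted p = 1.15e-14, against adjusted p = 0.377 with an estimated correlation). Its pair medians lay between −1.09 and −0.79 in articular cartilage and between −4.83 and −2.16 in growth plate. The fit uses 1 variance per gene for both tissues, so the growth plate spread enters the articular error. The lack of calls over all genes therefore does not show that articular matrix genes were unchanged. Among prehypertrophic and hypertrophic genes, Col10a1 and Scin, which encodes an actin-severing protein, fell, and 9 of 11 did not pass. That list had a median of −0.13 (camera adjusted p = 0.000334, against adjusted p = 0.225 with an estimated correlation). Of 12 growth plate signalling genes, Fgfr3, a fibroblast growth factor receptor (−1.89 ± 0.30), and Sfrp5 fell, and Bmpr1b was also lower when adjusted over the list alone, 3 in all. Its median was −0.45 (camera adjusted p = 1.42e-06, against adjusted p = 0.377 with an estimated correlation). Frzb, a Wnt antagonist, was the 1 gene to fall of 15 articular and superficial zone genes (−1.73 ± 0.24). Nog, which encodes the BMP antagonist noggin, was the 1 gene to fall of 20 Wnt and BMP genes (−1.44 ± 0.25). Adjusted over the list alone, 3 Wnt and BMP genes were higher and 2 lower.

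Lists of markers of other cells had at most 1 gene past limma over all genes in articular cartilage, and the pairs of several differed in sign. The 17 fibroblast and tendon genes had a median of 0.74 (camera adjusted p = 0.000364, against adjusted p = 0.455 with an estimated correlation), with 0 past limma over all genes and 3 higher adjusted over the list alone (Lum, Dpt and Pi16). The erythroid and macrophage lists had medians of 1.06 and 1.05, and the adipocyte list one of 0.82 (camera adjusted p = 0.01004 each, against adjusted p = 0.679, 0.679 and 0.588 with an estimated correlation). Lpl, the 1 adipocyte gene called, no longer passed after median ratio scaling (adjusted p = 0.145) or quantile normalisation (0.135). The cell cycle list had a median of 0.50 (camera adjusted p = 0.0480, against adjusted p = 0.823 with an estimated correlation) and skeletal muscle one of −0.71 (camera adjusted p = 0.000371, against adjusted p = 0.679). In the Sox9 day 7, Sox9 day 14 and labelled Sox8 Sox9 pairs in order, the medians were 1.66, −1.21 and 2.39 for erythroid, 2.27, 1.06 and −0.43 for macrophage, 1.21, −0.47 and 1.10 for cell cycle and 0.57, −0.15 and −2.54 for muscle genes, so the last pair carries the muscle value. Of 14 matrix degrading enzymes and inhibitors, 6 were higher and 1 lower adjusted over the list alone and 0 over all genes, with Mmp3, which encodes stromelysin, at 1.60 and Timp3, a metalloproteinase inhibitor, at −1.59. That list did not pass camera (adjusted p = 0.0890), but did after quantile normalisation (0.0102) and after median ratio scaling (0.0258). The other lists held no called gene and did not pass camera, with medians of 0.27 for chondrocyte transcription factors, 0.57 for neutrophils, 0.25 for B cells, 0.18 for endothelial cells, −0.11 for hypoxia and glycolysis and 0.00 for osteoclasts. The neutrophil list passed camera after quantile normalisation (adjusted p = 0.0383) but not after median ratio scaling (0.0687). Ebf1 of the B cell list was higher adjusted over the list alone. The transcription factor, osteoblast and osteocyte, and immediate early and stress lists had medians above 0, at 0.27, 0.11 and 0.16, while camera's direction was down, and the osteoblast median was −0.03 after median ratio scaling. The articular count rested on few libraries: limma called 24 genes in the Sox9 sets alone, 2 from the 6 articular libraries alone (1925 at an unadjusted p under 0.05), and 6 to 101 when 1 library was left out. With a block for each pair it called 12, and Vcan (adjusted p = 0.0645), Lpl (0.123), Tnfaip2 (0.129), Sbno2 (0.131), Omd (0.0645) and Fgfr3 (0.107) were no longer among them.

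In growth plate, most cartilage matrix genes and part of the hypertrophic genes fell in mutants, among them Col10a1 and Cdkn1c, while Ngp and Igkc were among the genes that rose. Col10a1 fell from 3637 ± 1283 to 45.1 ± 28.3, a log2 fold change of −6.49 ± 0.35 (limma, Benjamini-Hochberg adjusted p = 1.71e-05). Cdkn1c, which encodes the cell cycle inhibitor p57 (chromosome 7, 143458339 to 143461050), fell from 130.2 ± 26.6 to 9.66 ± 0.43, a change of −3.60 ± 0.18 with the same adjusted p. Matn3, which encodes the matrix protein matrilin-3, fell from 663 ± 165 to 18.2 ± 20.4 (−5.86 ± 0.69), and Ucma, a secreted cartilage protein, from 338 ± 58.2 to 20.04 ± 17.7 (−4.76 ± 0.64). Ngp, which encodes a neutrophil granule protein, rose from 8.66 ± 5.64 to 248 ± 162 (4.71 ± 1.03), and Igkc, the immunoglobulin kappa constant region, from 2.86 ± 2.02 to 93.7 ± 50.8 (4.57 ± 1.05).

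With limma and Benjamini-Hochberg adjustment, 1580 genes passed in growth plate, 1165 higher and 415 lower in mutants, and 1578 had the same direction in the 3 pairs. The split depended on the scaling. The median log2 fold change of all genes was 0.20, and scaling to the median ratio called 1467 genes, 726 higher and 741 lower, while quantile normalisation called 1285, 606 higher and 679 lower. Sox9 fell by 1.55 ± 0.43 (limma, Benjamini-Hochberg adjusted p = 0.0460) and Sox8 fell by 2.42 ± 0.43 (adjusted p = 0.00875). The Sox9 call held in 5 of 10 alternatives and in 2 of 12 fits without 1 library.

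Of 24 cartilage matrix genes, 22 fell, 0 rose and 2 did not pass, and 23 were lower adjusted over the list alone. After median ratio scaling 22 were lower, and after quantile normalisation 18. Col2a1, the main cartilage collagen, went from 17065 to 1772 (−3.50), Col9a1 from 1740 to 115 (−4.46), Col9a3 fell by 4.32 ± 0.69, and Matn1 went from 47.7 to 1.20 (−4.41). The list's median was −3.38 (camera adjusted p = 4.58e-31, against adjusted p = 0.127 with an estimated correlation). Of 11 prehypertrophic and hypertrophic genes 7 fell and 0 rose, and 9 were lower adjusted over the list alone. Besides Col10a1 and Cdkn1c, Ihh, the Indian hedgehog signal of prehypertrophic cells (−3.07), Panx3, a channel protein (−2.42), and Pth1r, the parathyroid hormone receptor (−1.37), fell, while Mmp13, collagenase 3, had 0.91 and Mef2c, a transcription factor of hypertrophy, had 0.21 without passing. Its median was −1.37 (camera adjusted p = 6.37e-13, and adjusted p = 0.0109 with an estimated correlation), the list whose call held with an estimated correlation in this comparison. Among 11 chondrocyte transcription factors, Foxa2 (−2.69), Foxa3 (−1.97) and Nkx3-2 (−2.12) fell and Runx1 (1.63) and Arid5b (1.14) rose; 4 were lower and 2 higher adjusted over the list alone. That median was −0.38 (camera adjusted p = 0.0201, against adjusted p = 0.641 with an estimated correlation, and 0.0793 after median ratio scaling). In the Sox9 day 7, Sox9 day 14 and Sox8 Sox9 pairs it was 0.09, −0.63 and −1.07.

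Signalling and tissue-identity genes went both ways or partly down in growth plate. Of 12 growth plate signalling genes, Hhip and Ptch1, both hedgehog-binding proteins, Fgfr3 and Sfrp5 fell, 4 also adjusted over the list alone, and 8 did not pass. The median of that list was −0.44 (camera adjusted p = 0.000370, against adjusted p = 0.641 with an estimated correlation). In the Sox9 day 7, Sox9 day 14 and Sox8 Sox9 pairs it was 0.39, −0.94 and −1.16, so the first pair differed in sign. Of 20 Wnt and BMP genes 5 rose and 4 fell, or 6 and 4 adjusted over the list alone, with Smad6, an inhibitory Smad, at 1.90 ± 0.23 and Chrdl1, a BMP antagonist, at −2.01 ± 0.37. Of 15 articular and superficial zone genes 5 rose and 2 fell, over all genes and adjusted over the list alone, including Thbs4 (1.93) and Vit (−2.21), against 3 and 2 after either scaling. Of 14 matrix degrading enzymes and inhibitors Adamts9 rose (1.08) and Timp3 fell (−1.66), against 4 and 2 adjusted over the list alone. The articular, Wnt and BMP, cell cycle and skeletal muscle lists had medians of 0.55, 0.17, 0.03 and 0.64 while camera's direction was down, and the first 2 held both directions; the Wnt and BMP and cell cycle medians turned to −0.01 and −0.16 after median ratio scaling.

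Part of the bone, stromal, neutrophil and macrophage genes rose beside the fall of the matrix genes. Of 22 osteoblast and osteocyte genes 9 rose and 2 fell, or 13 and 2 adjusted over the list alone. Col1a1, the collagen of bone and fibrous tissue, went from 4970.1 to 14137 (1.66), Mepe, a matrix protein of osteocytes, rose by 2.26 ± 0.45 and Tnn, which encodes tenascin-W, by 2.70 ± 0.70. The falls were Smpd3 (−1.33) and Alpl (−0.91), which act in mineralisation. That list's median was 1.48 (camera adjusted p = 0.0188, against adjusted p = 0.641 with an estimated correlation). Of 17 fibroblast and tendon genes 7 rose, including Col3a1 (3.17 ± 0.78) and Postn, which encodes periostin (2.88 ± 0.70), against 9 higher and 1 lower adjusted over the list alone (median 1.07, camera adjusted p = 0.0698, against adjusted p = 0.656 with an estimated correlation, and 0.00915 after median ratio scaling and 0.00247 after quantile normalisation). Of 13 neutrophil genes 8 rose and 0 fell, or 11 and 0 adjusted over the list alone. S100a8 and S100a9, the calprotectin subunits, went from 8.77 to 132 and from 20.2 to 231, and Camp and Ltf, which encode granule proteins, rose by 3.89 ± 0.79 and 3.94 ± 0.84 (median 3.18, camera adjusted p = 0.000130, against adjusted p = 0.641 with an estimated correlation). Of 11 macrophage genes 5 rose, or 10 adjusted over the list alone, with Lyz2, lysozyme, at 2.97 ± 0.46 and C1qa, a complement subunit, at 2.13 ± 0.51 (median 1.52, camera adjusted p = 0.00172, against adjusted p = 0.641 with an estimated correlation). After either scaling 3 macrophage and 7 osteoblast and osteocyte genes were higher.

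Markers of the remaining cells gave few growth plate calls. Of 9 osteoclast genes Itgb3 rose (1.28), or 5 adjusted over the list alone (median 0.74, camera adjusted p = 0.0348, against adjusted p = 0.641 with an estimated correlation). Of 11 erythroid genes Alas2, which starts haem synthesis in red cells, rose (2.07), or 5 adjusted over the list alone (median 1.94, camera adjusted p = 0.0572, against adjusted p = 0.727 with an estimated correlation, and 0.00848 after median ratio scaling). Of 6 B cell genes Ebf1 rose (1.62), or 3 adjusted over the list alone. Of 12 endothelial genes Egfl7 (0.97) and Vwf (0.81) rose, both also adjusted over the list alone, and of 7 adipocyte genes Lpl rose (1.12), or 2 adjusted over the list alone. After median ratio scaling and after quantile normalisation 0 erythroid and 0 endothelial genes passed over all genes, and Itgb3 of the osteoclast list passed only after the latter. Of 21 immediate early and stress genes Fosl2 rose (0.87) and Fosb fell (−2.63), also adjusted over the list alone (median −0.17, camera adjusted p = 0.00535, against adjusted p = 0.641 with an estimated correlation). Of 17 hypoxia and glycolysis genes Ndrg1 rose, from 3.48 to 13.1, and Eno1 fell (−0.86), against 1 and 2 adjusted over the list alone. None of 18 cell cycle and 15 skeletal muscle genes passed limma, over all genes or adjusted over the list alone. The growth plate count fell to 945 without the set block, to 274 in the Sox9 sets alone and to 0 with limma on the 6 growth plate libraries alone, where 2755 genes had an unadjusted p under 0.05, and was 658 to 1927 when 1 library was left out. With a block for each pair, Sox9 (adjusted p = 0.0779), S100a9 (0.0716), Postn (0.0686), C1qa (0.0562), Adamts9 (0.0586), Itgb3 (0.0756), Alas2 (0.0814), Egfl7 (0.0797) and Vwf (0.0647) no longer passed.

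**Figure D2:**
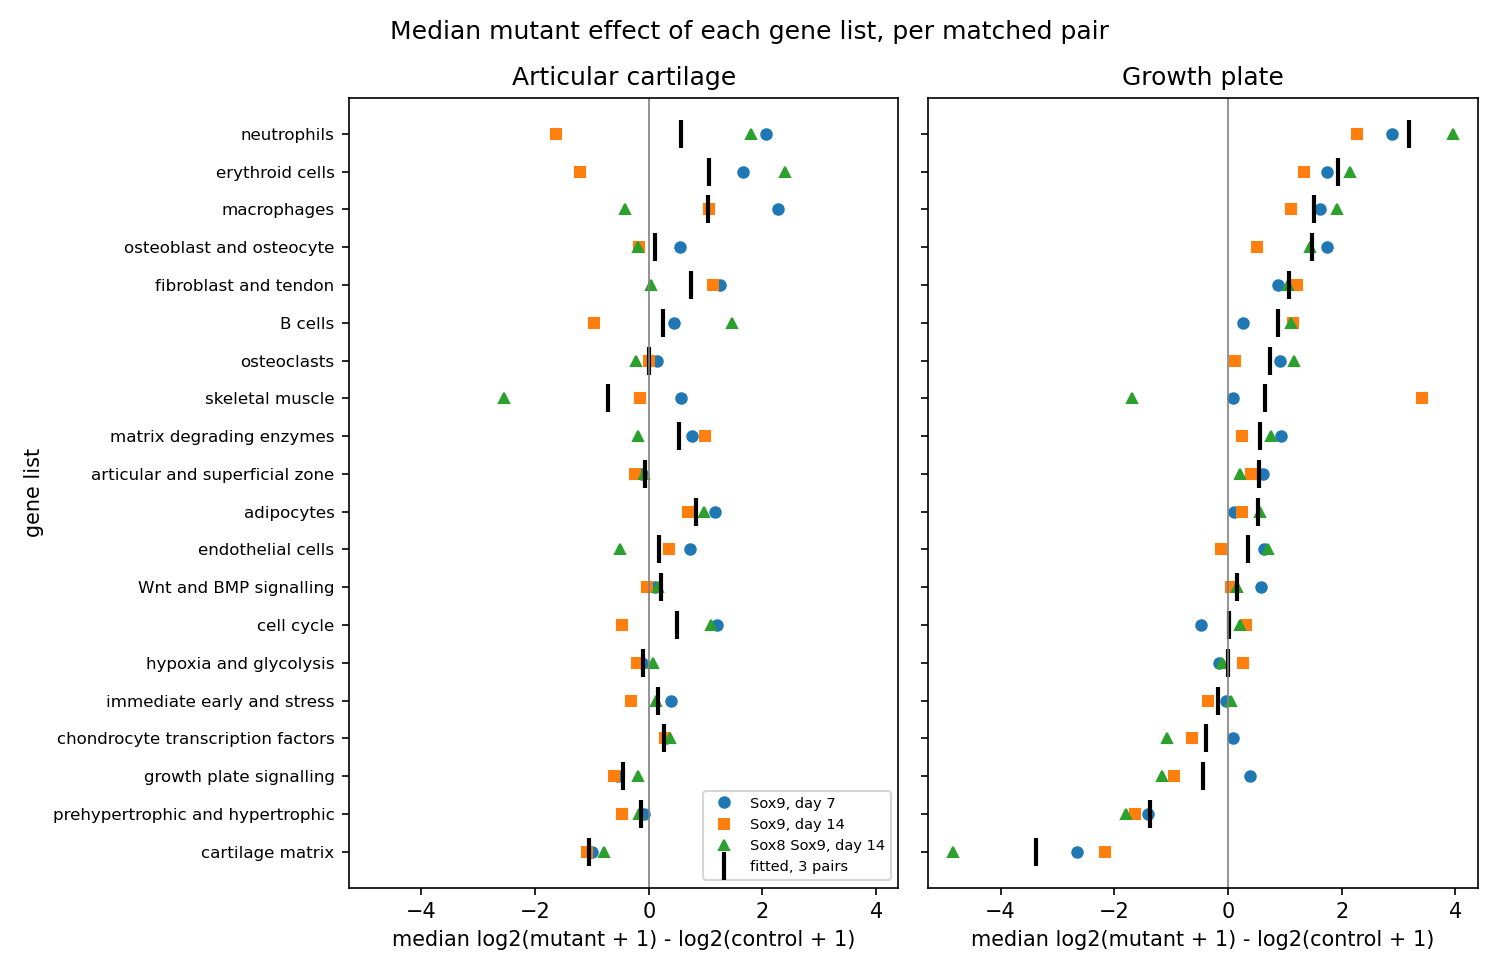
Median mutant effect of each gene list (log2 of mutant value + 1 minus log2 of control value + 1) in the 3 matched pairs of each tissue; coloured points are pairs and the black tick is the median of the fitted effects. In growth plate the cartilage matrix list lies at −3.38 and the neutrophil list at 3.18 in the fit.

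Controls of the 2 tissues differed in single genes such as Prg4 and Cilp on the articular side and Col9a1 and Matn3 on the growth plate side. Prg4, which encodes the joint lubricant lubricin (chromosome 1, 150449412 to 150466165), was 27235 ± 4520.5 in articular and 17.3 ± 17.0 in growth plate controls (mean ± SD, n = 3 each), a growth plate minus articular log2 difference of −11.01 ± 0.69 (limma, Benjamini-Hochberg adjusted p = 0.000128). Cilp, a cartilage matrix protein (−8.35 ± 0.85), Gas1, a hedgehog co-receptor (−6.50 ± 0.23), Clu, the chaperone clusterin (−6.25 ± 0.33), Serpina3n (−5.87 ± 0.36) and Sod3, extracellular superoxide dismutase (−5.82 ± 0.24), were also higher in articular cartilage. Col9a1, a collagen IX chain, was 2.19 ± 0.21 in articular and 1740 ± 655 in growth plate controls (9.03 ± 0.41). Matn3 (8.35 ± 0.64), Epyc, a small proteoglycan (5.67 ± 0.42), Lect1, now named Cnmd and encoding chondromodulin (5.62 ± 0.89), Panx3 (5.55 ± 0.17) and Ppa1, a pyrophosphatase (5.48 ± 0.40), were higher in growth plate.

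With limma and Benjamini-Hochberg adjustment, 1896 genes passed between the control tissues, 627 higher in growth plate and 1269 higher in articular cartilage, all in the same direction in the 3 sets. The median difference of all genes was −0.10, and scaling to the median ratio called 1972 genes, 913 higher and 1059 lower in growth plate, while quantile normalisation called 1902, 899 higher and 1003 lower. Sox9 differed by 0.03 ± 0.44 (limma, Benjamini-Hochberg adjusted p = 1, with −0.13 after quantile normalisation) and Sox8 by 0.48 ± 0.47 (adjusted p = 0.588), and neither passed. The count was 1058 in the Sox9 sets alone and 866 from the 6 control libraries alone, and leaving out 1 library at a time gave 894 to 2068. Of the named genes Ltf lost its call with set and 4 cells (adjusted p = 0.0570). The Ltf call held in only 1 of 10 alternatives and in 2 of 12 fits without 1 library.

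Of 24 cartilage matrix genes 16 were higher and 1 lower in growth plate, against 16 and 2 adjusted over the list alone (median 2.57, camera adjusted p = 6.05e-12, against adjusted p = 0.415 with an estimated correlation). Of 11 prehypertrophic and hypertrophic genes 7 were higher and 1 lower, against 7 and 2 adjusted over the list alone, with Pth1r at 4.83 ± 0.26 (median 2.49, camera adjusted p = 5.02e-06, against adjusted p = 0.137 with an estimated correlation). Of 15 articular and superficial zone genes 12 were lower in growth plate, also adjusted over the list alone, and 0 higher (median −2.96, camera adjusted p = 1.00e-08, against adjusted p = 0.168 with an estimated correlation). Of 17 hypoxia and glycolysis genes 11 were lower in growth plate (7 after median ratio scaling and 8 after quantile normalisation), or 16 adjusted over the list alone, including Egln3, an oxygen-sensing hydroxylase (−3.58 ± 0.18), and Ndrg1 (−2.45 ± 0.25); the median was −1.11 (camera adjusted p = 3.08e-07, against adjusted p = 0.322 with an estimated correlation). Of 21 immediate early and stress genes 6 were lower, or 7 adjusted over the list alone, including the heat shock gene Hspa1b (−3.43 ± 0.33) and the phosphatase gene Dusp1 (−2.61 ± 0.26), and 2 were higher (camera adjusted p = 0.0728). Of 18 cell cycle genes Ccnb2 (1.46) and Plk1 (1.21) were higher in growth plate, also adjusted over the list alone, but the list's medians in the 3 sets were 1.90, −0.51 and 0.63 (camera adjusted p = 0.000411, against adjusted p = 0.673 with an estimated correlation).

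Among 11 chondrocyte transcription factors 3 were higher in growth plate, including Runx3 (3.70) and Nkx3-2 (3.57), and 3 lower, with the same counts adjusted over the list alone. Growth plate signalling had 4 lower of 12, including the natriuretic peptide receptor gene Npr2 (−2.64) and Sfrp5 (−2.42), against 3 higher and 5 lower adjusted over the list alone. Wnt and BMP genes had 5 higher and 5 lower, including Chrdl1 (3.50) and Grem1 (−4.95), against 6 and 5 adjusted over the list alone. Matrix degrading enzymes had 5 higher and 4 lower of 14, including Mmp9 (4.48) and Mmp3 (−2.95), against 7 and 6. Osteoblast and osteocyte genes had 9 higher and 1 lower, with Smpd3 at 3.61 and Sost, which encodes sclerostin, at −2.87, against 9 and 3 adjusted over the list alone (camera adjusted p = 0.000106, against adjusted p = 0.444 with an estimated correlation). Osteoclast genes had 6 higher of 9, including Acp5, the phosphatase TRAP, at 4.06, and the proton pump gene Atp6v0d2 at 2.38, against 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000120, against adjusted p = 0.415). Endothelial genes had 5 higher and 1 lower of 12, including Kdr and Cdh5, against 7 and 1 (camera adjusted p = 0.000106, against adjusted p = 0.444). Neutrophil genes had 5 lower of 13 in growth plate, with Lcn2 at −3.30 and Ltf at −2.83, against 7 adjusted over the list alone (camera adjusted p = 0.000277, against adjusted p = 0.489). Macrophage genes had 2 higher and 3 lower of 11, including Cd14 (−3.93) and Lyz2 (−2.32), against 2 and 7, fibroblast and tendon genes 1 higher and 3 lower of 17, including Col3a1 (−3.72) and Dcn (−3.44), and B cell genes 1 lower of 6, Ebf1 (−1.17), the last 2 with the same counts adjusted over the list alone. Erythroid, adipocyte and skeletal muscle lists had none past limma. The transcription factor, fibroblast, and Wnt and BMP medians were −0.18, −0.09 and −0.03 while camera's direction was up, and the last 2 turned to 0.04 and 0.07 after median ratio scaling.

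The difference between the mutant effects of the 2 tissues was tested directly. Cdkn1c stayed at 14.6 in articular controls and 13.2 in articular mutants while it fell in growth plate, a difference of −3.46 ± 0.24 (limma interaction, Benjamini-Hochberg adjusted p = 0.00387). Il17b, a cytokine gene, had 61.0 and 2.37 in growth plate controls and mutants against 1.65 and 1.59 in articular cartilage (−4.18 ± 0.35). Fgfr2, a fibroblast growth factor receptor, went from 9.26 to 29.8 in growth plate and from 42.8 to 26.9 in articular cartilage (2.26 ± 0.25). In all, 27 genes passed, 7 with a higher and 20 with a lower effect in growth plate. Limch1 (2.39), Col13a1 (2.01) and Csrp1 (1.80) were among the first and Col9a1 (−4.53), Ppa1 (−4.41), Matn1 (−4.25) and Panx3 (−2.32) among the second, of which Col9a1, Matn1 and Panx3 were near the lowest listed value in articular cartilage. The Sox9 difference was −1.48 ± 0.62 (limma, Benjamini-Hochberg adjusted p = 0.440) and the Sox8 difference −0.56 ± 0.67 (adjusted p = 0.797). The call was fragile: limma called 0 genes in the Sox9 sets alone (1270 at an unadjusted p under 0.05) and 0 to 4 when any 1 library was left out. With set and 4 cells Col13a1 (adjusted p = 0.186) and Col9a1 (0.0708) no longer passed.

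Cartilage matrix, with 2 genes called and 9 lower adjusted over the list alone, and prehypertrophic and hypertrophic genes, with 2 called and 5, had medians of −1.79 and −1.90 for that difference (camera adjusted p = 9.74e-14 and 7.62e-06, against adjusted p = 0.649 and 0.131 with an estimated correlation). Osteoblast and osteocyte genes had a median of 0.99, with 7 higher and 2 lower adjusted over the list alone, and neutrophil genes 1.60, with 7 higher (camera adjusted p = 0.00223 and 3.46e-05, against adjusted p = 0.656 and 0.649). Osteoclast, cell cycle, stress and skeletal muscle lists had medians of 0.76, −0.52, −0.28 and 1.34 (camera adjusted p = 0.00242, 0.00561, 0.0150 and 0.0105, against adjusted p = 0.649, 0.790, 0.649 and 0.790). The other 12 lists did not pass camera. Of these, the macrophage list (camera adjusted p = 0.0903) did pass after quantile normalisation (0.0477) and after median ratio scaling (0.0320). In the 3 sets the medians were −1.60, 0.74 and −0.89 for cell cycle and 0.00, 3.89 and 0.77 for muscle genes, so the cell cycle sets differ in sign and 1 set carries the muscle value. Cartilage matrix had −1.26, −0.94 and −3.82, prehypertrophic and hypertrophic genes −1.33, −1.24 and −1.82, osteoblast and osteocyte genes 0.70, 0.32 and 1.84, and osteoclast genes 0.43, 0.29 and 1.69. These were largest in the Sox8 Sox9 set, whose articular Sox9 value goes against its label. Neutrophil genes had 0.97, 3.61 and 1.95 and stress genes −0.37, −0.53 and −0.29, largest in the Sox9 day 14 set. In direct comparison of calls, 12 of the 23 articular rises were also called higher in growth plate and 14 of the 29 articular falls lower there, with 0 called in opposite directions. Independent lists of these sizes would share 1.82 and 0.818 genes. Fisher's exact tests gave two-sided p = 3.42e-08 and 8.58e-15, though genes are not independent of each other. Both effects also come from 1 fit with 1 variance per gene, so a gene with a small variance is easier to call in both tissues. Col10a1, Sfrp5, Frzb, Scin, Fgfr3, Nog and Lpl were among the shared genes. Across genes the fold changes of both tissues had r = 0.388 and rho = 0.314. No library is in both comparisons, but both use the same 3 sets and the labels do not say whether the tissues come from the same animals, so part of the overlap can come from shared animals or handling, which the Fisher tests ignore.

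**Figure D3:**
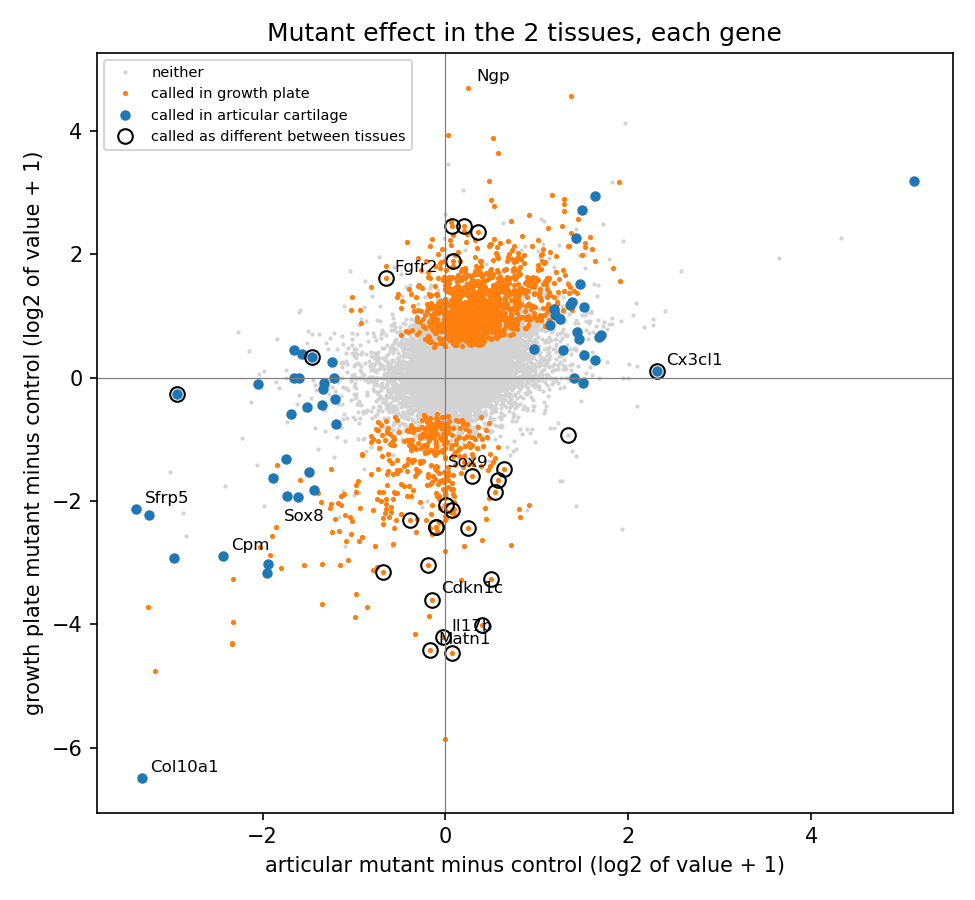
Mutant minus control log2(value + 1) of each of the 14712 genes in articular cartilage (horizontal) and growth plate (vertical); orange points passed in growth plate, blue points in articular cartilage and black rings passed the test of the difference. Col10a1 is low on both axes, at −3.32 and −6.49, and Cdkn1c on the vertical axis at −3.60.

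Days 7 and 14 of the Sox9 pairs could be described only, with 1 library per genotype, day and tissue. In growth plate, Chad, a matrix protein gene, had log2 ratios of mutant to control of −3.15 at day 14 and −0.05 at day 7, and Cytl1, a secreted cartilage protein, −4.01 and −0.81. Serpina1d had −2.88 and 1.15. The growth plate cartilage matrix list had a median ratio of −2.16 at day 14 and −2.66 at day 7, with a median difference of 0.41, at percentile 96.2 of 10000 random lists matched on expression. Chad and Cytl1 belong to this list, but 20 of its 24 genes had a higher ratio at day 14 and only 4 a lower one. Growth plate signalling differed by −1.24 and osteoblast and osteocyte genes by −1.05, both at percentile 0, against a median of −0.29 for all genes. Skeletal muscle genes differed most, by 2.82 with 15 of 15 higher at day 14, at percentile 100. In articular cartilage Serpina3n (2.46), Fmod (2.43) and Dpt (2.22) had higher ratios at day 14. Hbb-y differed by −7.05, which comes from day 7 alone (3.20 in the control and 555 in the mutant), since both day 14 libraries were at 1. The articular matrix list differed by 0.01, at percentile 30.1, while neutrophil genes differed by −4.21, at percentile 0.

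At day 14 the Sox8 Sox9 growth plate pair had lower ratios of matrix genes than the Sox9 pair. The matrix list had a median ratio of −4.83 against −2.16, a median difference of −2.71 with 22 of 24 genes lower, at percentile 0. Fxyd2, which regulates the sodium pump, had −7.08 against −1.60 and Scrg1, a gene of chondrogenic cells, −6.00 against −0.60. Phex, an osteocyte endopeptidase, had 2.29 against −0.01, and Txnip (2.18) and Ifi30 (2.12) also differed upward. The prehypertrophic and hypertrophic list differed by −0.08, osteoblast and osteocyte genes by 0.93, neutrophil genes by 1.16 and osteoclast genes by 1.17. The largest list difference was that of skeletal muscle, −4.75 with 15 of 15 genes lower, at percentile 0, so these pairs differed in more than cartilage genes. In the articular pair labelled Sox8 Sox9, against the Sox9 pair, the matrix list differed by 0.25, at percentile 99.4, neutrophil genes by 3.79, skeletal muscle genes by −2.06 and fibroblast genes by −1.12, with Dpt (−4.45), Aebp1 (−3.74), Clic5 (−3.58) and Col3a1 (−3.53) lower. A direction drawn from that pair carries the mismatch of its Sox9 value with its label. Its Sox8 value (15.3 in the control and 8.66 in the mutant) and its Acan value (1038 and 347) were lower in the mutant. Xist, which is expressed from the inactive X chromosome, was 1 in the 8 libraries of the Sox9 sets and 61.2 to 76.5 in the 4 libraries of the Sox8 Sox9 set, and the Y-linked Ddx3y was 11.8 to 22.0 and 1, so sex and genotype cannot be separated in this comparison. The reporter allele named for the Sox9 sets only cannot be separated from them either.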

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

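The tests of other sample splits were chosen before their results were seen; the tests of cell markers, of room to fall and of the Sox8 Sox9 pair were all chosen after, the room-to-fall test was redefined more than once after earlier versions had been seen, and the bound for marrow RNA was loosened once 11 of 12 had been seen.

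The mutant effect differed between the tissues in 27 genes by limma's interaction test. The growth plate effect minus the articular effect was 2.39 for Limch1, 2.26 for Fgfr2, 2.01 for Col13a1 and 1.80 for Csrp1. It was −4.53 for Col9a1, −4.41 for Ppa1, −4.25 for Matn1, −4.18 for Il17b, −3.46 for Cdkn1c and −2.32 for Panx3. By camera with a preset correlation, 8 lists also differed, with medians of −1.79 for cartilage matrix, −1.90 for prehypertrophic and hypertrophic genes, 0.99 for osteoblasts and osteocytes, −0.52 for cell cycle, −0.28 for immediate early and stress genes, 1.60 for neutrophils, 0.76 for osteoclasts and 1.34 for skeletal muscle. With an estimated correlation none of the 8 passed, with adjusted p from 0.131 to 0.790, and fry called the prehypertrophic and hypertrophic list alone (adjusted p = 0.000144).

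Of the 20 genes with a lower effect in growth plate, 18 fell more there and the other 2, Cx3cl1 and Gm20412, had higher values in articular mutants. Values held at 1 may leave no room for an articular fall. For 12 of the 18, the articular controls lay above 1 by more than 2 standard errors of the articular effect. The mutants of all 12 did too, by at least 4.09, but genes called for the difference had small articular changes, so this decides little. For Cdkn1c, Ppa1, Nid2, Zcchc5, Wnt11 and Rras2 the controls lay less far above 1 than the growth plate fall (log2 1.67 against 4.01 for Ppa1). An equal articular fall could not have been measured in them. For Hspg2, Loxl3, Eps8, Peg3, Aldh1a3 and Slc35e3 the controls lay farther above 1 than that fall (5.38 against 2.07 for Hspg2), which left room for an equal fall. For the other 6, Col9a1, Matn1, Panx3, Il17b, Capn6 and Nrgn, the articular controls lay within 2 standard errors of 1, so an effect of tissue and the floor cannot be told apart. A tissue difference in the response to the mutation stays open and was not tested apart from this.

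By camera with a preset correlation, neutrophil, macrophage, osteoblast and osteoclast lists were higher in growth plate mutants (adjusted p = 0.641 each with an estimated correlation) and cartilage matrix lower (0.127 with it), while the erythroid list had 1 of 11 genes called and did not pass (0.0572). The neutrophil list exceeded the endothelial list by 2.63 ± 0.54 (SD over 3 pairs). A lower share of chondrocyte RNA that raises all other cell types alike would not part them. These 2 lists were chosen after their medians were seen, so this argues against an equal rise of those 2 only. The osteoclast list lay closer to the endothelial list. In the Sox9 day 7, Sox9 day 14 and Sox8 Sox9 pairs, osteoclast medians were 0.91, 0.13 and 1.16 and endothelial medians 0.64, −0.12 and 0.71. A lower share of chondrocyte RNA stays open for such lists, as does a change in which cells were captured. For marrow and blood RNA in the captured tissue, 11 of 12 list medians lay above that of all genes, the exception being B cells in the Sox9 day 7 pair (−0.0402); growth plate controls also had 6 of 13 neutrophil genes above a value of 2, and Ngp, S100a9 and Lyz2 reached 248, 231 and 133 in mutants, so RNA from neighbouring marrow and marrow cells in altered tissue cannot be told apart. For bone tissue in the capture, the osteoclast list lay above all genes in 3 of 3 pairs, by at least 0.13 in median, as that explanation needs. The rise of this list is part of the pattern to be explained, so it gives the explanation no support of its own. In growth plate controls 7 of 9 osteoclast genes and 21 of 22 osteoblast genes were also above 2. Replacement of growth plate by bone and marrow in the mutants is a biological candidate explanation that was not tested, nor was how much of the matrix fall a smaller share of chondrocytes may account for.

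The cartilage matrix list was lower in the Sox8 Sox9 growth plate pair than in the Sox9 pair at day 14, by a median of −2.71. Dilution of chondrocyte RNA by RNA of other cells would lower the prehypertrophic and hypertrophic genes alike, if those cells did not express them. Their median difference was −0.0815 (SD 1.17, n = 11 genes, with permutation p = 0.000130 for the difference of the list means across genes, which are not independent). The lists thus moved apart between these pairs. With 1 library per genotype and tissue, and a test chosen after the values were seen, this does not decide whether dilution is the cause. The chondrocyte transcription factor list had a median of −1.07 in the Sox8 Sox9 pair and −0.63 in the Sox9 pair. Lists of other cells went both ways, such as neutrophils (3.95 and 2.27) and skeletal muscle (−1.68 and 3.42). Some prehypertrophic and hypertrophic genes, such as Mmp13 and Mef2c, are also expressed in bone cells, which limits this test. The osteoblast and osteocyte list had medians of 1.44 in the Sox8 Sox9 pair and 0.52 in the Sox9 pair, so bone RNA may have differed between them. Sex or another difference between the sets of animals may contribute; the matrix list had a median log2 ratio of −0.0613 between the growth plate controls of the sets, against 0.0011 for all genes, but the sets differ in sex and each has 1 library, so this and the Sox8 alleles cannot be told apart. Sox9 itself went from 308 to 36.0 in this growth plate pair, against 335 to 148 in the Sox9 pair at day 14. Sox8 also fell in that Sox9 pair, from 21.7 to 4.93. The pairs thus differ in Sox9 as well. A reporter allele is named in the column headers for the Sox9 sets only. The effect of losing Sox8 in addition was therefore not isolated.

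Other splits of the 6 libraries or blocks of each comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 52 genes in articular cartilage and the highest other split 1; in growth plate these were 1580 and 0, between control tissues 1896 and 0, and for the tissue difference 27 and 1. In each comparison 1 of the 10 splits, the real one, gave as many genes. Every other split mixed the compared groups, so a real difference between them would enter the residual spread and lower the count of that split. Without a real difference, few calls would be made as well. Low counts in the other splits therefore decide nothing, and no conclusion is drawn from them.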

How the results depend on the processing

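The mean of at least 5, median ratio scaling and protein-coding genes were alternatives chosen after seeing the data; the others were planned. Count-based alternatives did not apply, and dropping the filter changed nothing because it removed 0 genes. Genes called both in the chosen fit and in an alternative had the same direction in all alternatives run. Of 2447 values of named genes under an alternative, 1896 kept their side of the threshold, 549 kept their direction but no longer passed and 2 newly passed. Direction changed in 9, all of them of Sox9 or Sox8 values that passed in neither fit, and in 0 called values. The 2 that newly passed were values of Sox8 in articular cartilage.

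Articular calls were 52, and 29 without the set block, 12 with a block for each matched pair, 24 in the Sox9 sets alone and 2 in the 6 articular libraries alone, 1 of which was among the 52. Growth plate calls were 1580, and 945 without the set block, 274 in the Sox9 sets alone and 0 in the 6 growth plate libraries alone (limma, 2755 at an unadjusted p under 0.05). Control tissue calls were 1896, and 1058 in the Sox9 sets alone and 866 in the 6 controls alone. Tissue difference calls were 27, and 15 with 0.1 added, 0 in the Sox9 sets alone (limma, 1270 at an unadjusted p under 0.05) and 63 among protein-coding genes. List calls with an estimated correlation were 0, 1, 0 and 0 in these comparisons, and fry called 1, 7, 7 and 1. In growth plate 5 of the 9 lists called by camera were among the fry calls, without growth plate signalling (adjusted p = 0.156), transcription factors (0.371), stress genes (0.403) and osteoclasts (0.0581). In control tissues 6 of 9 were, without cell cycle (0.339), neutrophils (0.0616) and endothelial cells (0.0854). Fewer libraries enter some of these fits; otherwise the cause was not tested. The alternatives left counts of 38 to 57, 1069 to 1756, 1524 to 2051 and 20 to 40 elsewhere. Adding 0.25 moved the described matrix list difference of the Sox8 Sox9 growth plate pair from −2.71 to −2.82.

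Leaving out 1 library gave 6 to 101 articular calls: 6, 15 and 22 without the articular Sox9 day 7 control, Sox9 day 14 control and the library labelled Sox8 Sox9 mutant, 6 and 7 without the articular Sox9 day 7 and day 14 mutants, 101, 27 and 27 without the growth plate controls of the day 7, day 14 and Sox8 Sox9 sets, and 22 and 80 without the growth plate day 7 and Sox8 Sox9 mutants. Growth plate calls ranged from 658 to 1927: 658, 871 and 776 without the growth plate controls of those sets in order, and 739 and 784 without the Sox9 day 7 and Sox8 Sox9 mutants. Control tissue calls ranged from 894 to 2068: 894, 1056 and 1018 without an articular and 900.0, 1063 and 1030.0 without a growth plate control of those sets. Tissue difference calls ranged from 0 to 4 and so fell without any 1 library. A group left with fewer libraries is assumed to vary like the others. Depth is unknown, and genes at the lowest value of 1 hide any further fall.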

Other observations

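The comparison of tissue calls with growth plate mutant calls was chosen after those calls were seen. Of the 627 genes higher in growth plate than in articular controls, 188 were lower in growth plate mutants and 54 higher. Independent lists of these sizes would share 17.7 and 49.7. Of the 1269 genes higher in articular controls, 260 were higher and 35 lower in growth plate mutants, against 100 and 35.8 for independent lists. The fold changes of the comparisons had r = −0.368 across genes, against −0.500 in 50 simulations without effects, because both use the growth plate controls. Their covariance was −0.165 against a simulated −0.0501 (SD 0.00180), a difference of −0.114. Simulated errors were independent between genes, unlike those of real genes, so this SD is too small to judge the difference by. With 3 growth plate controls they could not be split into parts of 2 libraries, and how much of the overlap comes from the shared controls was not separated.

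Blood and marrow markers varied between the articular pairs. The neutrophil list had median log2 ratios of 2.07, −1.63 and 1.80 in the Sox9 day 7, Sox9 day 14 and labelled Sox8 Sox9 pairs, and the erythroid list 1.66, −1.21 and 2.39. Skeletal muscle genes differed in the growth plate pairs, with medians of 0.09, 3.42 and −1.68 in the same order. Among the described genes, structural RNAs moved far between single libraries, for example Snord15b at 501 in the Sox9 day 14 growth plate mutant and 1 in its control, and U2 at 580.3 in the articular Sox9 day 14 control and 6.26 in its mutant. Scarna2 was 144 in that control and 1 in that mutant, and Gm17316 was 158 and 1. Gm12563 differed by 2.08 between the articular Sox9 pairs of the days. Copies of U1, 5S_rRNA (−5.81 between the growth plate pairs at day 14) and Metazoa_SRP (3.46 between the days) varied likewise. The other Y-linked genes read, Kdm5d, Uty and Eif2s3y, were at 1 in the 4 libraries of the Sox8 Sox9 set and at 2.58 or more in the others.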
